A study of Mus musculus with 4 samples.

How the data were processed

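Whole mouse embryos at embryonic day 9.5 were compared between 2 genotypes on Affymetrix arrays, with 4 arrays in all. Per the labels, RNA of 6 embryos lacking Cop1 was mixed into 1 pool and RNA of 6 control embryos, wild type or heterozygous, into another. Each pool was divided into 2 portions before labelling, and each portion went onto 1 array. The 2 arrays of a genotype are therefore technical portions of the same RNA. The p-values of single genes and probe sets below rest only on the spread between such portions. Those of gene lists and families set the members against all other genes. All tests compare 2 RNA pools, with no replicate check of the genotype itself.

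Per the labels' protocols, embryos were lysed directly after dissection, RNA was purified on columns and its integrity was checked on a Bioanalyser, and biotin-labelled cRNA was made from total RNA. The authors deposited 1 table of expression values for the 4 arrays. The values are on the log2 scale and were made with RMA in the R package affy, per the submitters' processing notes. The versions of both, and the mapping of probes used, are not given in the sources used here. RMA corrects the background, gives every array the same distribution of probe intensities and combines the probes of a probe set into 1 value, so a change of total RNA per embryo leaves no trace in these values. The values were used as deposited, with no further scaling.

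The table held 45101 probe sets, of which 64 were Affymetrix control probe sets. These were kept out of the tests, and 45037 probe sets were tested. Probe sets were named from the platform's annotation table. It lists 34945 of the tested probe sets with 1 gene and 932 with several genes, which were given no name, and it does not list the other 9160, which are unnamed here. Symbols were compared through gene numbers with a RefSeq gene table of assembly GRCm38.p6, which matched 34741 of the probe sets with 1 gene and changed 0 symbols. Each gene was represented by its probe set with the highest mean over the 4 arrays, which gave 18193 genes. Probe sets of the same gene can disagree. For genes named under the rule below, the text states where no other probe set was called or one was called in the opposite direction.

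Differences are given as the null pool minus the control pool. They were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on all tested probe sets with the genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all 45037 probe sets. A gene was said to have risen or fallen when its adjusted p was under 0.05 and its fold was at least 1.5. The 39 gene lists were tested for a shift against all other genes with limma's camera, two-sided, at a preset correlation of 0.01 between members. Adjustment was over the 39 lists, and an adjusted p under 0.05 was a call. The same test was run with the correlation estimated for each list, which had 2 residual degrees of freedom. Each list's median was also placed among the medians of 10000 random lists of the same size drawn from genes of like mean level. Member calls adjusted over the list alone are given where their count differs from that over all genes. For arrays there is no read depth, and their number limits the precision.

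The groups, the tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Under that rule the text names Cop1, the 12 genes with the largest rise and the 12 with the largest fall among those past both limits, up to 4 called members of each list with the largest change, and 2 members with the largest change where a list had no called member. Clone and prediction names were passed over in the lists of 12, as was a gene with another probe set called in the opposite direction. Among the rising genes 1 was passed over for its name, and among the falling genes 3 for their names and 1 for an opposite probe set. Other genes are named as chosen after their values were seen. The lists hold 638 different genes, of which 587 were measured.

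The fit was tested on simulated data with the real mean levels and the spread between portions, in which 50 probe sets were changed at each of 4 fold sizes. For this comparison of 4 arrays, both limits were passed by 36% of probe sets changed 1.5-fold. They were passed by 96% of those changed 2-fold and by 100% of those changed 3-fold or 4-fold. A 1.5-fold change lies on the fold limit itself, so many such probe sets must miss it, and 70% of them passed the adjusted p alone. Among the unchanged ones of the 45037 probe sets there were 3 false calls. The list test called 10 of 10 simulated lists of 20 genes shifted by 0.5 log2 units and 0 of 40 unshifted lists, with the preset and with the estimated correlation. In this simulation the noise was independent between probe sets, and no gene outside the shifted lists was changed. In the data many other genes differ, so neither the probe set result nor the list result gives the power or the false calls of its test there.

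The alternatives were: centring each array on its median, applying quantile normalization once more, the replicate number as a block, leaving out each array in turn, eBayes with a trend and robust prior, leaving out the dimmest 40% of probe sets, averaging the probe sets of a gene, leaving out probe sets that can match several transcripts by their name, other fold limits, limma's treat, counts without a test, and lists without members shared with another list. Centring on the hybridisation spikes and on the poly-A spikes was added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No genome sequence was used here, so no positions of probes or genes are given, and the RefSeq table served only for names and for the order of genes along a chromosome.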

Results

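Gene expression was measured in whole mouse embryos at embryonic day 9.5, when the heart beats, somites form along the trunk and the first neurons arise in the neural tube. The embryos either lacked Cop1 or came from the control group of wild-type and heterozygous embryos. COP1 is an E3 ubiquitin ligase that marks transcription factors such as JUN and members of the ETV family for degradation. RNA of 6 embryos per genotype was mixed into 1 pool, and 2 portions of each pool went onto separate arrays, so that every value below rests on 2 arrays of 1 pool. The 4 arrays had median log2 expression values of 6.03 and 6.03 for the control portions and 6.10 and 6.09 for the null portions, over 45101 probe sets. Across probe sets, which are not independent replicates, Pearson's r was 0.998 between the control portions, 0.998 between the null portions and 0.980 to 0.982 between arrays of different genotype. The control portions differed by at least 1.5-fold in 133 probe sets (0.295%) and the null portions in 143 (0.318%), whereas the means of the 2 pools differed by that much in 6266 of 45037 probe sets (13.9%).

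Cop1 itself was lower in the null pool. Its only listed probe set read 11.35 and 11.26 on the control arrays and 9.67 and 9.77 on the null arrays. The means were 11.30 ± 0.06 in the control pool and 9.72 ± 0.07 in the null pool (log2 expression, SD, n = 2 portions). Cop1 thus fell by 1.58 log2 units (SE 0.08), which is 2.99-fold (limma, adjusted p = 0.000728). On the null arrays the Cop1 probe set still read above the upper quartiles of all probe sets, 8.12 and 8.13. Where this probe set lies relative to the deleted part of the gene is not known here, and a probe set outside it would not measure the loss of that part.

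The genes with the greatest rise in the null pool included several that respond to low oxygen. Adm, which encodes the vasodilator peptide adrenomedullin, rose from 7.84 ± 0.11 to 11.38 ± 0.10 (log2, SD, n = 2 portions), 11.7-fold, and Stc2, which encodes the secreted glycoprotein stanniocalcin 2, rose 11.4-fold. Pfkp, a phosphofructokinase of glycolysis, rose 7.62-fold, Ndrg1, a stress-induced gene, 6.03-fold, and Bhlhe40, a transcriptional repressor, 7.38-fold. Hspa1a, an inducible heat shock chaperone, rose 7.20-fold and the nuclear noncoding RNA Malat1 6.65-fold, and Slc7a3, a transporter of cationic amino acids, rose by 2.81 log2 units. Among the genes with the greatest fall, Lig4, the ligase of DNA end joining, differed by -2.21 log2 units, and albumin (Alb) and Pik3r3, a regulatory subunit of phosphoinositide 3-kinase, each differed by -2.09.

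In all, 652 genes rose and 1467 fell among 18193 genes (limma, adjusted p under 0.05 and at least 1.5-fold), so 30.8% of the changed genes had risen. This balance depends on the probe set that stands for a gene, as over all 45037 probe sets 3044 rose and 3134 fell (49.3% rises), and over the other probe sets of named genes 1487 rose and 1366 fell (52.1% rises). The other genes among the 12 with the greatest rise were Taf15, an RNA-binding protein gene (3.70, SE 0.23), Gdap10 (3.23, SE 0.14), Ier3, an immediate early gene (2.91, SE 0.08), and Ndufa4l2, which encodes a mitochondrial protein (2.64, SE 0.09). Taf15 read 5.49 ± 0.48 in the control pool (SD, n = 2 portions), and its other probe set rose by 1.21. The 12 genes with the greatest fall also held Dido1 (-2.56, SE 0.08), the homeobox gene Homez (-2.34, SE 0.10), Tlcd4 (-1.99, SE 0.18), Serpina6, the gene of the corticosteroid-binding globulin (-1.89, SE 0.07), Kbtbd8, a ubiquitin ligase adaptor gene (-1.84, SE 0.07), Lipo3 (-1.80, SE 0.08), Haspin, a histone kinase gene (-1.77, SE 0.07), and the zinc finger genes Zfp84 (-1.93, SE 0.16) and Zfp709 (-1.80, SE 0.14). The adjusted p-values of these 24 genes lay between 0.000549 and 0.00223. For Dido1, 2 of the other 4 probe sets fell as well (-0.89 and -0.65), and the remaining 2 read 0.47 and 0.15 without a call. No other probe set of Tlcd4 or Zfp84 was called. Without control replicate 1, a different probe set stood for Zfp84 and gave -0.23 (adjusted p = 0.226). Centring the arrays on the poly-A spikes, a scaling chosen after the data were seen, gave 380 rises and 2848 falls, 11.8% of calls being rises, and moved the median of all genes from -0.02 to -0.22. These counts rest on the fold limit alone, as every gene past it also had an adjusted p under 0.05 in that fit, and the fold limit alone gave 655 and 1483 without centring. They also rest on a spike difference between pools that was no larger than that between the control portions, whose poly-A medians were 7.40 and 7.63. Of the 2119 changed genes, 1229 had several probe sets, and of these 608 had another one called in the same direction and 70 one called in the opposite direction.

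**Figure D1:**
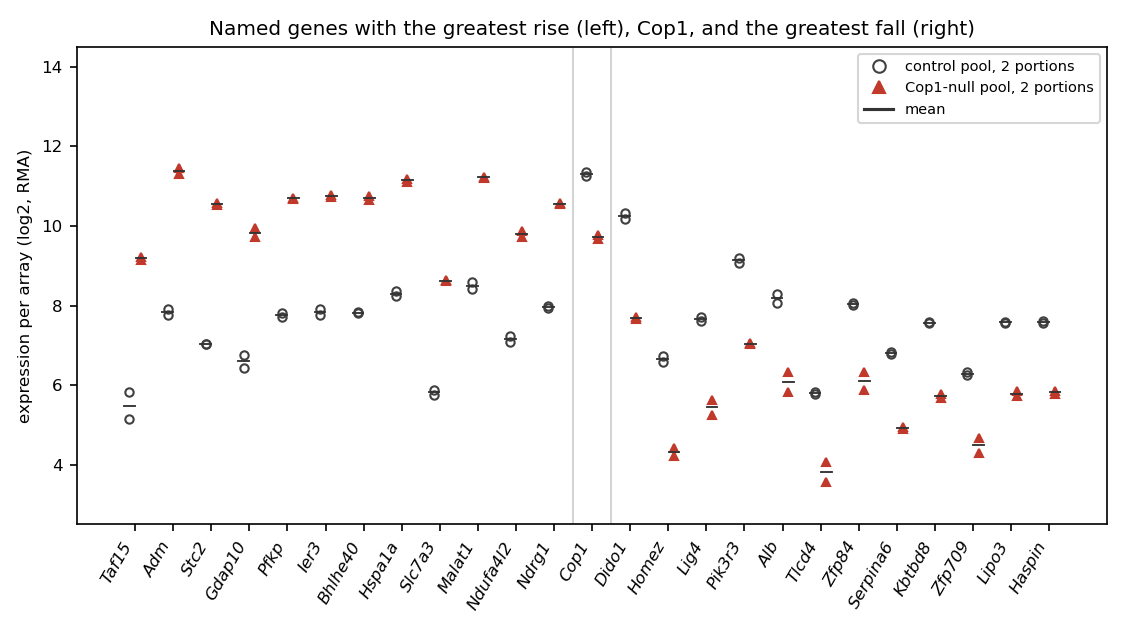
Log2 expression (RMA) of Cop1 and of the 12 named genes with the greatest rise and the 12 with the greatest fall, with each array as a point (circles, control portions; triangles, null portions) and the mean of each pool as a line. For all 25 genes the 2 portions of a pool lie closer to each other than to the other pool, with Cop1 at a mean of 11.30 in the control pool and 9.72 in the null pool. Apart from Cop1, the genes were chosen for large differences between pools, so this separation follows from the choice.

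Genes of the response to low oxygen and of glycolysis rose almost throughout. Of 28 measured members, 25 rose and 0 fell, and the median difference was 1.59 log2 units, or 3.02-fold. Adm (3.55), Pfkp (2.93), Ndrg1 (2.59) and Ddit4 (2.59), an inhibitor of mTORC1 signalling, led the list. The 3 members without a call, named after their values were seen, were also positive, Pkm at 0.51, Ldha at 0.45 and Pgam1 at 0.45. The list's shift had an adjusted p of 2.5e-22 in limma's camera at the preset correlation and an adjusted p of 0.282 with an estimated correlation.

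Targets of ATF4 in the integrated stress response, which serve amino acid supply and are switched on when translation is restrained, rose in 15 of 19 cases, with 0 falls and a median difference of 1.07. Vldlr, a lipoprotein receptor gene, rose from 8.21 to 10.60 (log2), Chac1, a glutathione-degrading enzyme gene, by 2.02, and Ddit3, the gene of the transcription factor CHOP, by 1.85. Of this list Ddit4 also stands on that of hypoxia, Sesn2 on that of p53 targets and Trib3 on that of COP1 partners. The shift had an adjusted p of 5.9e-12 at the preset correlation (limma's camera) and an adjusted p of 0.282 with an estimated correlation. Chaperones of the endoplasmic reticulum held 1 rise among 14 members, that of Herpud1 (0.94), a gene of protein degradation at that organelle. Their median was 0.01 (adjusted p = 0.539).

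Immediate early and heat shock genes were higher as a list, with 7 rises and 1 fall among 18 members and a median of 0.32. Ier3 (2.91), the chaperone genes Hspa1a (2.85) and Hspa1b (2.37) and the transcription factor gene Atf3 (3.03-fold) rose furthest, while Dnajb1, another heat shock gene, fell by 0.73 on the log2 scale. The adjusted p was 0.000505 (limma's camera), and the adjusted p was 0.303 with an estimated correlation. In the AP-1 family of transcription factors, 5 of 13 members rose and 0 fell, with a median of 0.36. These were Atf3 (3.03-fold), Jdp2 (1.37), Maff (1.16) and Junb (1.15), and Fosl2 (0.69), which was named after its value was seen. The AP-1 list had an adjusted p of 0.00414, an adjusted p of 0.303 with an estimated correlation, and an adjusted p of 0.058 once members shared with other lists were left out. AP-1 target genes gave 2 rises, the angiogenic factor Vegfa (2.16) and the heme oxygenase gene Hmox1 (2.83-fold), and 2 falls, the G1 cyclin gene Ccnd1 (-0.91) and Sphk1 (-0.60), among 14 members (median 0.13, adjusted p = 0.148). With poly-A spike centring the median of this list turned to -0.07. Sphk1 missed the limits without control replicate 1 (-0.56, adjusted p = 0.105), without control replicate 2 (-0.63, adjusted p = 0.0894) and without null replicate 1 (-0.44, adjusted p = 0.0485).

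Endothelial genes were higher in the null pool, with 9 rises and 0 falls among 26 members and a median of 0.43. Flt1, a receptor of VEGF, rose by 1.80, the transcription factor gene Sox17 by 1.23, the Notch ligand gene Dll4 by 0.80 and the adhesion molecule gene Icam2 by 0.78. The adjusted p was 1.4e-05 (limma's camera), and the adjusted p was 0.282 with an estimated correlation. Embryo sex markers were higher too, with 3 rises among 4 members and a median of 0.79. Xist, the RNA that coats the inactive X chromosome of females, rose by 0.94, and the Y-linked genes Kdm5d and Eif2s3y, which only males carry, by 0.83 and 0.76. The representative probe set of Uty, also Y-linked, read -0.06 without a call, and of its other 3 probe sets 1 was called, at 1.32. The sex list had an adjusted p of 0.0199 (limma's camera), and an adjusted p of 0.347 with an estimated correlation. As the list joins markers of both sexes, its shift does not measure a difference in the share of males.

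Genes of early neurons were lower in the null pool. Of 25 measured members, 15 fell and 0 rose, with a median difference of -0.78. The bHLH genes Neurod4 (-1.63), Neurod1 (-1.29) and Nhlh2 (-1.26), which act in neurons as they form, and the acetylcholine receptor subunit gene Chrna3 (-0.99) fell furthest. The adjusted p was 5.5e-08 (limma's camera), and the adjusted p was 0.282 with an estimated correlation. Among neural progenitor and regional genes, 9 fell and 1 rose of 21, with a median of -0.30 that missed the threshold (adjusted p = 0.0658). Neurog1, which drives cells towards a neuronal fate, fell by 1.58, the forebrain gene Emx2 by 1.16, Fabp7 by 1.09 and Dbx1 by 1.07, and the rise was that of Nkx6-2 (0.76), named after its value was seen. In the neural crest list 2 of 14 members fell, Tfap2b (-1.29) and Dlx1 (-1.06), with a median of -0.01 (adjusted p = 0.792).

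Genes of cholesterol synthesis were lower, with 5 falls and 0 rises among 16 members and a median of -0.46 (limma's camera, adjusted p = 1.4e-05, and adjusted p = 0.282 with an estimated correlation). Mvk (-0.90), Sqle (-0.80), Nsdhl (-0.76) and Idi1 (-0.69), all enzyme genes of the pathway, fell, and so did Msmo1 (10.68 to 9.67), whose other probe set was called in the opposite direction. Genes of somites and segmentation were lower as well, with 5 falls among 18 members and a median of -0.37 (adjusted p = 0.00701, and adjusted p = 0.303 with an estimated correlation). These were Pax1 (-1.59), a marker of the sclerotome, the myogenic factor genes Myog (-1.49) and Myf5 (-0.72), Meox2 (-0.71) and, named after its value was seen, Tcf15 (-0.64). The posterior Hox genes, which pattern the trunk, the tail and the limbs, had a median of -0.44 with 3 falls among 17 members (adjusted p = 0.00414, and adjusted p = 0.303 with an estimated correlation). Of these, Hoxa11 (-0.64) kept its call when any array was left out but lay under the fold limit with quantile normalization applied once more (-0.58). Hoxa10 (-0.80) missed the threshold without control replicate 1 (-0.84, adjusted p = 0.0556) and without control replicate 2 (-0.76, adjusted p = 0.0688). Hoxc10 (-0.60) missed the limits without control replicate 2 (-0.49, adjusted p = 0.0447), null replicate 1 (-0.63, adjusted p = 0.0577) and null replicate 2 (-0.57, adjusted p = 0.0728).

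Cell cycle genes were slightly lower, with 4 falls among 24 members and a median of -0.22 (adjusted p = 0.00414, and adjusted p = 0.303 with an estimated correlation). The cyclin E genes Ccne1 (-1.57) and Ccne2 (-0.62), the mitotic kinase gene Plk1 (-0.75) and Rrm2 (-0.63), a subunit of ribonucleotide reductase, fell, and Ccne2 lay under the fold limit without control replicate 2 (-0.54, adjusted p = 0.0352). Mitochondrial respiration held 2 falls among 20 members, the cytochrome c gene Cycs (-0.91) and Sdhb (-0.65), and its median was -0.13 (adjusted p = 0.0282, and adjusted p = 0.347 with an estimated correlation). That call was lost without control replicate 2 (median -0.12), null replicate 1 (-0.13) or null replicate 2 (-0.12). In limma's camera it was also lost with quantile normalization applied once more (-0.10, adjusted p = 0.126) and without the dimmest 40% of probe sets (adjusted p = 0.0906). The median stood at percentile 14.4 of matched random lists.

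**Figure D2:**
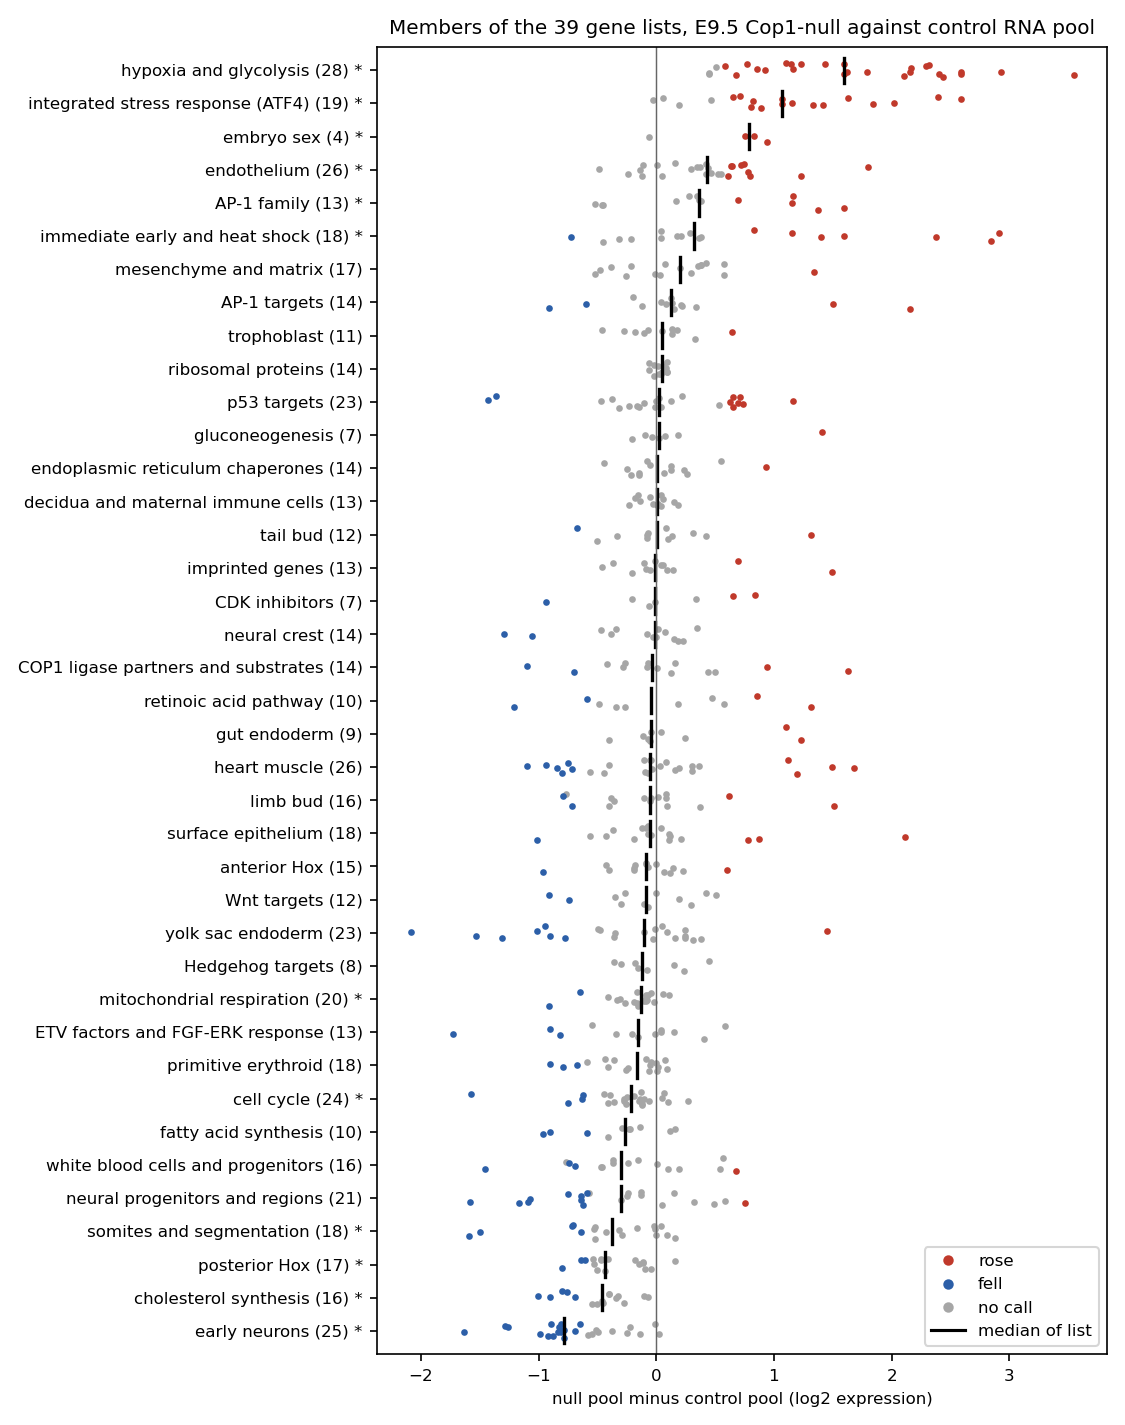
Null minus control difference (log2 expression) of every measured member of the 39 gene lists, with the number of members in brackets, the median of each list as a bar and an asterisk at the 12 lists called by limma's camera at the preset correlation. The medians of the called lists run from -0.78 for early neurons to 1.59 for hypoxia and glycolysis.

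The other lists did not pass the test as a whole, and most of them held changed members. Of the partners and substrates of the COP1 ligase, the pseudokinase gene Trib3 (1.63) and the transcription factor gene Cebpb (0.94) rose while Trib1 (-1.10) and Trib2 (-0.70), the adaptor genes through which COP1 reaches C/EBP proteins, fell, among 14 members (median -0.03, adjusted p = 0.66). Of the ETV factors and the FGF-ERK response genes, Etv5 (-1.73), Etv4 (-0.82) and Dusp4 (-0.90) fell and 0 rose, among 13 (median -0.16, adjusted p = 0.463). Targets of p53 went both ways, with 7 rises and 2 falls among 23 (median 0.02, adjusted p = 0.441). Eda2r rose by 1.17 and Tnfrsf10b by 0.73, and Trp53inp1 (-1.43) and Tigar (-1.36) fell, although no other probe set of Tigar was called. Tnfrsf10b missed the limits without control replicate 1 (0.57, adjusted p = 0.117), control replicate 2 (0.90, adjusted p = 0.0541) or null replicate 2 (0.56, adjusted p = 0.118). Of 7 CDK inhibitors, Cdkn1b (0.84) and Cdkn1a (0.65) rose and Cdkn2c (-0.94) fell (median -0.01, adjusted p = 0.459).

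Heart muscle genes divided, with 4 rises and 6 falls among 26 (median -0.05, adjusted p = 0.946). The natriuretic peptide genes Nppb (1.68) and Nppa (1.49), the myosin gene Myh7 (1.20) and Ankrd1 (1.12) rose. The gene of largest fall, named after its value was seen, was Pln (-1.10), which encodes the calcium pump regulator phospholamban. Surface epithelium gave 3 rises, the keratin genes Krt19 (2.11), Krt18 (0.87) and Krt8 (0.78), and 1 fall, Krt14 (-1.01), among 18 (median -0.06, adjusted p = 0.601). In gut endoderm Sox17 (1.23) and Hhex (1.10) rose among 9 (median -0.05, adjusted p = 0.442), and in mesenchyme and matrix Tagln (1.34) rose among 17 (median 0.20, adjusted p = 0.0726). The limb bud list held 2 rises and 2 falls among 16 (median -0.05, adjusted p = 0.792), and 3 falls adjusted over the list alone. Pitx1 (-0.79) and Hand2 (-0.72) fell, Prrx1 (1.51) rose with another probe set called in the opposite direction, and Alx4 (0.62) lost its call without control replicate 1 (0.72, adjusted p = 0.0512), control replicate 2 (0.51, adjusted p = 0.0952) or null replicate 2 (0.49, adjusted p = 0.0845). In the tail bud list the retinoic acid-degrading enzyme gene Cyp26a1 rose (1.31) and Sp8 fell (-0.68) among 12 (median 0.00, adjusted p = 0.573), the latter missing the limits without control replicate 2 (-0.58, adjusted p = 0.037) or null replicate 2 (-0.63, adjusted p = 0.051). Of 15 anterior Hox genes, Hoxb3 fell (-0.96) and Hoxb2 rose (0.60), the latter under the fold limit without null replicate 2 (0.58, adjusted p = 0.0308), with a median of -0.09 (adjusted p = 0.694).

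Fatty acid synthesis had 3 falls among 10 (median -0.26, adjusted p = 0.0658), in Fasn (-0.97), the fatty acid synthase gene, Elovl6 (-0.90) and Scd1 (-0.59), which was under the fold limit without control replicate 1 (-0.56, adjusted p = 0.0353) or null replicate 2 (-0.56, adjusted p = 0.0359). In gluconeogenesis Pck2 rose (1.41) among 7 (median 0.02, adjusted p = 0.441). The retinoic acid list held rises of Cyp26a1 (1.31) and the receptor gene Rarb (0.85) and falls of Aldh1a1 (-1.21) and Crabp2 (-0.59) among 10 (median -0.04, adjusted p = 0.692), Crabp2 being under the fold limit without control replicate 1 (-0.56, adjusted p = 0.0331). Of 13 imprinted genes, Meg3 (2.82-fold) and Igf2r (0.69) rose (median -0.01, adjusted p = 0.601). Of 12 Wnt targets, Ccnd1 (-0.91) and Nkd2 (-0.74) fell (median -0.09, adjusted p = 0.792). Among 8 Hedgehog targets 0 were called, with Foxc2 at 0.45 and Foxf2 at -0.36 (median -0.12, adjusted p = 0.946). Among 14 ribosomal protein genes 0 were called, with Rps18 at 0.09 and Rps19 at 0.09 (median 0.05, adjusted p = 0.349).

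Markers of blood and of the tissues around the embryo were also measured. In the yolk sac endoderm list, many of whose members are also transcribed in the early liver, 7 of 23 fell and 1 rose (median -0.11, adjusted p = 0.391). Alb (-2.09), the thyroxine carrier gene Ttr (-1.53) and the fibrinogen chain gene Fga (-1.31) fell, and Cubn (1.45) rose but missed the threshold without null replicate 1 (1.42, adjusted p = 0.081) or null replicate 2 (1.48, adjusted p = 0.0802). Of 11 trophoblast genes Ascl2 rose (0.64), with a list median of 0.05 (adjusted p = 0.595), and missed the threshold without control replicate 2 (0.45, adjusted p = 0.0967), null replicate 1 (0.54, adjusted p = 0.149) or null replicate 2 (0.74, adjusted p = 0.0915), while its other 2 probe sets rose by 1.09 and 1.14. Of 13 genes of decidua and maternal immune cells 0 were called, S100a8 reading -0.23 and Gzme 0.18 (median 0.00, adjusted p = 0.923). In the primitive erythroid list the erythroid transcription factor gene Klf1 (-0.79), the membrane protein gene Epb42 (-0.68) and Add2 (-0.90) fell among 18 (median -0.16, adjusted p = 0.0658). Add2 is covered by 5 probe sets that disagree, and it read -0.03 without control replicate 1 (adjusted p = 0.854) and 0.11 without control replicate 2 (adjusted p = 0.473). Of 16 genes of white blood cells and their progenitors, Myb (-1.45), Cd68 (-0.74) and Lyz2 (-0.69) fell and Pf4 (0.68) rose (median -0.30, adjusted p = 0.553), with 4 falls adjusted over the list alone.

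The control probe sets, which stand outside the tests, differed as well. The 3 probe sets of 18S ribosomal RNA were higher in the null pool, with a median difference of 1.27 (2.42-fold, range 1.12 to 1.66), and the 3 probe sets of B1 and B2 repeats by a median of 0.55 (range 0.12 to 0.94). The median difference was 0.05 for the hybridisation spikes, 0.19 for the poly-A spikes, 0.05 for beta-actin and 0.15 for Gapdh. Poly-A spike medians were 7.40 and 7.63 on the control arrays and 7.67 and 7.83 on the null arrays. Their difference between pools was thus no larger than that between the control portions, and the results of poly-A spike centring rest on it. The 5' minus 3' difference of the control transcripts, a sign of RNA integrity, changed by 0.01 for Actb, 0.02 for Gapdh, -0.40 for Tfrc and -0.07 for Pcx.

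**Figure D3:**
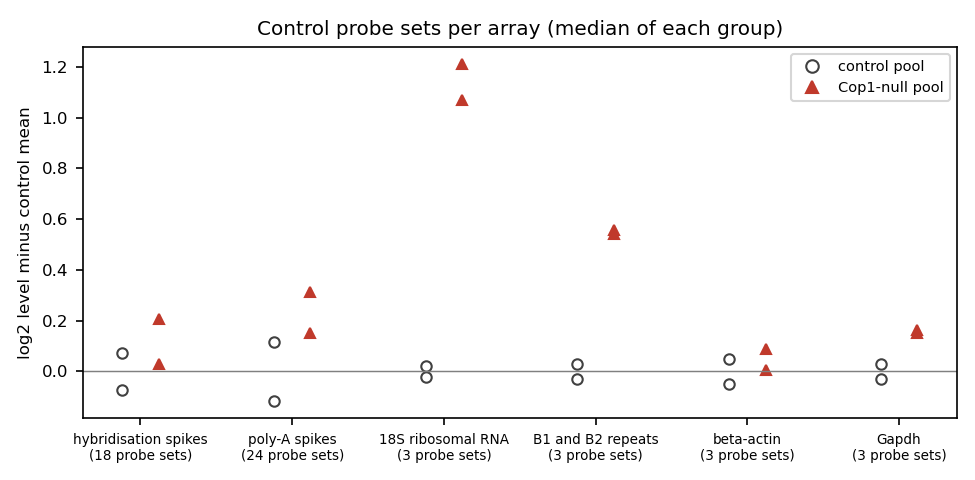
Median log2 level of each group of control probe sets on each array, given relative to the mean of the 2 control arrays (circles, control portions; triangles, null portions). The 18S ribosomal RNA group has the greatest difference, with medians of 11.56 and 11.61 on the control arrays and 12.65 and 12.80 on the null arrays.

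Of the 39 lists, 12 passed the camera threshold, 6 higher and 6 lower. With an estimated correlation and 2 residual degrees of freedom 0 lists passed in limma's camera, and 5 had an unadjusted p under 0.05. The estimated correlations of the 12 called lists ran from -0.083 (AP-1 family) to 0.037 (hypoxia and glycolysis). They come from differences between portions of the same pool and so hold technical spread only. How members vary together between embryos cannot be read from them, and they do not bear out the preset correlation. That test takes its p from a t distribution with 2 degrees of freedom, which makes small p-values rare. The loss of calls is therefore no sign of correlated members. The median, the mean and the test of the list differed in sign for COP1 partners, heart muscle, surface epithelium, gut endoderm, decidua, CDK inhibitors, the retinoic acid pathway and imprinted genes. Averaged over their probe sets, Etv4, Trib1, Trib2, Pitx1, Hand2, Tfap2b, Cdkn1b, Elovl6, Nkd2, Igf2r and Kdm5d lay under the fold limit, as did Hoxa10 (-0.27), Scd1 (-0.17), Sphk1 (-0.31), Add2 (-0.36) and Tnfrsf10b (0.57). With the poly-A spike centring, Cdkn1a (0.45), Pf4 (0.48), Icam2 (0.58), Krt8 (0.58), Igf2r (0.49), Eif2s3y (0.56), Tnfrsf10b (0.54), Hoxb2 (0.40), Alx4 (0.42) and Ascl2 (0.44) lay under the fold limit, as Hoxb2 (0.57) did with the hybridisation spikes. With quantile normalization applied once more, Hoxa11, Hoxc10, Alx4, Ascl2, Rrm2, Ccne2, Scd1 and Crabp2 did, and with each array centred on its median Hoxb2, Alx4 and Ascl2. Without probe sets that can match several transcripts by their name, Tnfrsf10b (0.41) and Cubn (0.46) did. No other probe set was called for Jdp2 (0.12), Etv4 (-0.08), Trib1 (-0.05), Sphk1 (-0.03), Hoxa10 (0.25), Scd1 (0.25) and Tfap2b (0.25), where the value in brackets is that of the only other one. The same held for Tnfrsf10b, Dll4, Pax1, Pitx1, Hand2, Neurog1, Cubn, Cdkn1b, Cdkn1a, Mvk, Elovl6, Igf2r and Kdm5d, of which Hand2 (0.18) and Kdm5d (-0.02) had a probe set of opposite sign. Because the 2 arrays of each genotype share 1 RNA pool, the tests of genes set the difference of the pools against technical spread. The list tests set members against the other genes of the same 2 pools. In both, a difference in stage, sex or handling between the pools would be counted as well.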

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

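All of the tests in this part were chosen after the results had been seen.

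Among the 9160 probe sets not listed with a gene, which enter no comparison of named genes, 861 rose and 231 fell in the null pool, so 78.8% of their calls were rises. That share was 30.8% for the probe sets that stand for a gene and 52.1% for the other probe sets of named genes. At middle levels of expression the unlisted probe sets had a median difference of 0.17 and rose in 23.9% of cases, and all probe sets of named genes there had a median of -0.03 and rose in 8.60%. A bias of the normalization that depends on level would move both alike, but at matched levels the unlisted ones lay 0.075 higher (95% bootstrap interval 0.068 to 0.083), which argues against it as the whole cause. More unspliced or intergenic RNA in the null pool is a candidate explanation. The B1 and B2 repeat probe sets were all higher, with a median of 0.55. These repeats occur in introns and between genes but also elsewhere, and the 18S probe sets rose further (1.27). The repeats therefore cannot single out this explanation. RNA breakdown cannot be told apart from it, because the lowest 5' minus 3' change was -0.40, for Tfrc, while Actb and Gapdh lay near 0. A true effect of genotype stays open as well.

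The control probe sets of 18S ribosomal RNA, which no comparison uses, were higher in the null pool by a median of 1.27 log2 units, above both control arrays.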

How the results depend on the processing

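The centring on spike controls was chosen after the data were seen, and all other alternatives before. The numbers of genes that rose and fell, 652 and 1467, became 246 and 315 at a limit of 2-fold, 254 and 329 with limma's treat, 2192 and 3973 with no fold limit, each by the limit's own construction. They became 380 and 2848 with poly-A spike centring, by the fold limit alone as the p-values of that fit are of little use, which lowered the median of all genes from -0.02 to -0.22, and under each other alternative they stayed within 1.5 times (543 to 734 and 1103 to 1835). Leaving out each array gave 609 to 678 rises and 1274 to 1444 falls, and 6 to 6 lists higher and 5 to 7 lower, the lone array being assumed to vary like the other genotype. With a correlation estimated per list, in a test with 2 degrees of freedom, 0 lists were higher and 0 lower, where the preset one gave 6 and 6. Cop1 read between -1.53 and -1.78, and between -1.53 and -1.63 with an array left out (adjusted p = 0.013 to 0.0183). Portions of the control pool differed in 133 probe sets and those of the null pool in 143, which became 1 and 4 at 2-fold and 54 and 41 without the dimmest 40% of probe sets. The replicate numbers share only a number (the differences between portions correlated at 0.056 over probe sets). With them as a block, 647 genes rose and 1455 fell, 645 and 1449 of them shared with the unblocked fit, Cop1 stayed at -1.58 (adjusted p = 0.00692), and 6 lists were higher and 6 lower. Alx4 lost its call with the block (0.62, limma, adjusted p = 0.0509). Add2 turned from -0.90 to 0.060 with quantile normalization applied once more and ranged from -0.96 to 0.11 with an array left out, above 0 only without control replicate 2, because another of its 5 probe sets then had the highest mean. Of 2201 values of 130 named genes under the alternatives, 2023 kept their call or stayed without one, 174 lost the call and 2 gained it. Another 2 belonged to a called gene and changed sign. A change of sign was not counted for genes without a call or for list medians. Of 623 list values, 584 were kept, 21 lost the call and 18 gained it, and the causes were not tested.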

Other observations

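All of the tests in this part were chosen after the results had been seen, and the families were formed from the first letters of gene symbols.

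Beyond the lists, 5 of 172 gene families defined by symbol shifted as a whole in limma's camera at the preset correlation. Small nucleolar RNA host genes (Snhg) were higher, with 7 of 14 rising and a median of 0.56 (adjusted p = 0.00211, and adjusted p = 0.913 with an estimated correlation), led by Snhg17 (1.24), Snhg16 (1.10) and Snhg12 (1.08). Histone lysine demethylase genes (Kdm) were higher, with 7 of 18 rising and a median of 0.36 (adjusted p = 0.00413, and adjusted p = 0.913 with an estimated correlation), among them Kdm3a (1.43), Kdm7a (1.36) and Kdm5b (0.87). This family is not separate from the lists, as Kdm3a also stands on that of hypoxia and Kdm5d (0.83) on that of embryo sex. Both families stayed positive under every scaling tried, at 0.37 and 0.16 with poly-A spike centring. Genes of the large subunit of the mitochondrial ribosome (Mrpl) were lower, with 7 of 47 falling and a median of -0.28 (adjusted p = 0.00211, and adjusted p = 0.913 with an estimated correlation), led by Mrpl41 (-1.28) and Mrpl20 (-0.76). Those of the small subunit (Mrps) had 5 of 29 falling and a median of -0.30 (adjusted p = 0.00211, and adjusted p = 0.913 with an estimated correlation), namely Mrps18c (-0.77), Mrps24 (-0.68), Mrps12 (-0.67), Mrps6 (-0.59) and Mrps11 (-0.95), the last with another probe set called in the opposite direction. Genes of the regulatory particle of the proteasome (Psmd) had a median of -0.27 and 1 of 14 falling (adjusted p = 0.00232, and adjusted p = 0.913 with an estimated correlation), Psmd13 (-0.65), which also has a probe set called in the opposite direction. The medians of Mrpl, Mrps and Psmd were -0.31, -0.33 and -0.30 with centring on the hybridisation spikes and -0.48, -0.50 and -0.47 with centring on the poly-A spikes. Their calls were lost in those fits, but the p-values of spike-centred fits are of little use. Centring raised the median residual SD of the probe sets from 0.08 to 0.12 and 0.14, and limma then gave all probe sets the same variance. Zinc finger genes named Zfp held 16 rises and 59 falls among 336 genes, with a median of -0.19 that missed the threshold (adjusted p = 0.0863).

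Genes of hypoxia and ATF4 targets rose together. Tissue of the mother or of the membranes carried over with the null embryos would raise its own abundant transcripts, yet the highest median of the yolk sac, trophoblast and decidua lists was 0.048. Afp, the most abundant of the yolk sac markers, fell from 11.84 to 10.83. In that list 7 of 23 members fell and Cubn (1.45) rose, and Ascl2 of the trophoblast list rose in all 3 of its probe sets. These values show no broad rise of such markers. They cannot exclude carried-over tissue, because many of the yolk sac members, such as Alb and Ttr, are also transcribed in the early liver. A fall there could hide a rise. Of these markers, 14 of 23, 4 of 11 and 0 of 13 lay above the median level in the control embryos, and 0, 3 and 0 stand on another list. A longer time between dissection and lysis cannot be told apart from the genotype, since the median of Fos, Egr1, Ier2, Dusp1 and Nr4a1 was 0.21, with Nr4a1 at 0.83 and Ier2 at -0.32. An effect of the missing Cop1, directly or through an embryo that was failing or poorly supplied with oxygen, stays open as untested.

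Xist and the Y-linked genes Kdm5d and Eif2s3y were all higher in the null pool, while the representative probe set of Y-linked Uty was not. A different share of males would move Xist and the Y-linked genes in opposite directions. The joint rise of Xist (0.94, SE 0.07), Kdm5d (0.83, SE 0.08) and Eif2s3y (0.76, SE 0.06) argues against it as the only cause for these 3 genes. A different share beside another cause cannot be told apart, because Uty differed by -0.52 technical standard errors, the other genes were picked for having risen, and there is 1 pool per genotype. A shift shared by genes of like level cannot be told apart, as the 3 genes stood at percentiles 96.8 to 98.0 among the tenth of genes nearest in level, on both sides of the limit set for this test.

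Sequence of the strain in which the Cop1 allele was made may have been carried along on chromosome 1 and altered probe binding. Of the 200 measured genes nearest to Cop1, 34 were called, 8 rising and 26 falling, against a median of 23 in 143 overlapping windows of that size elsewhere, of which 3 held as many. Of the nearest 50 genes 7 were called, against a median of 6, so the hypothesis stays open.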
